A study of Rattus norvegicus with 25 samples.

How the data were processed

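Prefrontal cortex of wild-type Wistar rats was sampled at 5 ages with 5 libraries each. Per the labels' protocols, RNA was extracted with a lipid tissue kit, ribosomal RNA was depleted from 2.5 µg of RNA, and the remainder was fragmented, copied to cDNA and amplified with 10 PCR cycles. Libraries of about 300 bp were sequenced as 50 bp single-end reads on a HiSeq 2000 to about 29000000 reads per sample, per the labels' protocols. Depletion of ribosomal RNA keeps RNA without a poly(A) tail, so short non-coding RNAs can enter the libraries.

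The authors deposited 1 table of FPKM values, fragments scaled by transcript length and by the mapped fragments of the library, with 1 row per Ensembl gene ID and 1 column per library. Per the labels' protocols, reads were aligned to the rn4 rat assembly with GSNAP. Per the submitters' processing notes, the tools were BWA 0.6.1, bedtools and Cufflinks, with build rn4 and no role or order given, so which aligner made the deposited values is open. The annotation release, the strand setting, the handling of reads that map to several places and any filter are not given in the sources used here. FPKM is a relative unit: an abundant transcript in one library lowers the values of all others unless the scaling corrects for it. Genes that share reads with near-identical copies or overlap on the opposite strand carry uncertain values.

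Samples were grouped by the age in their labels. Columns were matched to libraries by the sample titles, and replicate numbers were given in accession order and only name a library. No pairs of columns were identical (0), and Spearman's rho between libraries over tested gene IDs was 0.859 to 0.982. Whole reads were sought for each gene ID, since its FPKM times the relative depth of a library is a whole multiple of the value of 1 read. Depth was taken from the mode of pairwise ratios among sparse gene IDs in 300 library pairs, 1 of which departed from the fitted depths. A gene ID counted as recovered when at least 95% of its values above 0 lay within 0.05 reads of a whole number, with values under 0.0001 FPKM read as 0. This held for 9468 of 14128 gene IDs (67%), and 99.92% of their values were whole within that tolerance. The search needed values above 0 in at least 15 libraries and tried at most 3000 reads for the lowest value. Sparse or very abundant gene IDs could therefore be missed. After random changes of 2% in each value, 0% of 2000 gene IDs drawn were recovered. On simulated reads, 596 of 600 gene IDs were recovered exactly. In the 50 pairs of libraries of the same age, the squared difference of recovered reads was 2.35 to 24.6 times that of counting noise, so no 2 libraries were counted as 1. Only counting noise was compared, so this does not show that each library came from a separate sample.

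The main test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 0.5). Gene IDs entered with at least 1 FPKM in at least 5 of the 25 libraries, which left 14128. All 25 libraries went into 1 fit with 1 mean per age and 20 residual degrees of freedom, with empirical Bayes moderation and a trend with mean level. Contrasts were P14 minus P8, P21 minus P14, P35 minus P21, P70 minus P35 and P70 minus P8, each two-sided with Benjamini-Hochberg adjustment over all gene IDs tested, and an F-test covered all 5 ages. A gene ID was called at an adjusted p under 0.05. A log2 change on this scale understates the change of gene IDs with low values. Step sizes are means over tested gene IDs of the squared difference of age means, less the variances of both means, with a delete-one jackknife SE. Single library measures were compared by exact permutation. Shuffled values came from 100 shuffles of the residuals among libraries. The chance of no overlap was computed from the possible orderings of the libraries, and the numbers for independent lists from the list sizes.

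The test was tried on simulated values with the real means and spreads, for P14 minus P8 with 200 of 14128 gene IDs changed. At a 1.5-fold change it recovered 59% with independent noise and 49.5% with the real structure between libraries, with 8 and 4 false calls. At a 2-fold change it recovered 87.5% and 84.5%, with 16 and 43 false calls.

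Before the data were examined, the design, the alternatives and the rule for naming genes were fixed. The rule took, for each step, the 5 gene IDs with the largest rise and the 5 with the largest fall, and for P70 minus P8 the 10 largest each way. Each needed an adjusted p under 0.05, no overlap between the libraries of both ages, at least 5 FPKM on average at the higher age, and a gene name outside a list of uninformative prefixes. The files do not pair the Ensembl IDs with names, so the last criterion was not used, and only the 2 largest rises and 2 largest falls from P8 to P70 are printed as IDs. For the same reason the gene lists and cell type markers fixed beforehand, and the tests of those lists, were not analysed here.

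Alternatives were pseudocounts of 0.1 and 1, no filter, a mean of at least 5 FPKM, quantile normalization, median-of-ratios scaling, equal FPKM totals, the first number of the sample title as a random block, robust moderation, the 10 libraries of each contrast alone, a log2 change of at least 1, and each library left out in turn. What the title numbers mark is not stated. Alternatives chosen after seeing the data left out the 3 libraries of lowest same-age correlation or the 2 shallowest. The log2 FPKM total as a covariate, only recovered gene IDs and limma-voom on the recovered reads were also chosen then. So were limma array weights and only gene IDs above 0 throughout. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for read recovery and plots.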

Results

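Transcript levels were measured by RNA sequencing in the medial prefrontal cortex, the front part of the cortex near the midline, of wild-type Wistar rats. Tissue was taken at postnatal days 8, 14, 21, 35 and 70, written P8, P14, P21, P35 and P70. Each age had 5 libraries, 25 in all, and the comparison asked which transcripts differ between these stages of postnatal life. The labels do not say that each library came from a separate animal, so p-values measure only the spread between these samples. The sex of the animals is not given in the sources used here. The deposited table lists 29516 gene IDs, of which 5277 were at 0 in every library. The files do not pair these IDs with gene names, and 0 of them matched the reference table used here. Groups of gene IDs are therefore described by direction, timing and level, and 4 IDs are given as examples.

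The number of gene IDs at 1 FPKM or more was 12693 to 13468 per library. It averaged 13325 ± 102 (SD, n = 5) at P8 and 13094 ± 245 (SD, n = 5) at P70, a difference that did not pass (exact two-sided permutation test, p = 0.0635, adjusted p = 0.262 over 6 library measures). FPKM totals ran from 472548 to 1649378, a 3.49-fold range. The 10 most abundant gene IDs held 27.7% to 64.5% of the total, with a mean of 49.5%. The deposited values are not counts, but whole reads could be recovered for 9468 of the 14128 gene IDs tested. These summed to 1906031 to 6848152 reads per library. Depth relative to the median library was lowest in P21 replicate 5, at 0.386, and P70 replicate 2, at 0.447, and highest in P21 replicate 4, at 1.31. The median recovered gene ID had 205 reads per library, and 574 had a median under 10 reads. These figures cover the recovered gene IDs only, and the search could miss sparse or very abundant ones.

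Over the 5 ages together, 7848 of the 14128 gene IDs tested differed (55.5%; limma moderated F-test, adjusted p under 0.05). The leading principal component held 34.5% of the variance and ordered the libraries by age up to P21. P8 libraries lay between -63.2 and -53.7 on it, P14 libraries between -21.5 and -11.1, and P21 libraries between 15.8 and 20.8. P35 and P70 libraries overlapped, at 21.5 to 35.1 and 25.2 to 33.8. The mean correlation with the other libraries of the same age was lowest in P14 replicate 2 (0.906), P14 replicate 5 (0.919) and P21 replicate 5 (0.931). The median SD between libraries of an age was 0.15 at P8, 0.242 at P14, 0.186 at P21, 0.222 at P35 and 0.219 at P70, on the log2 scale.

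**Figure D1:**
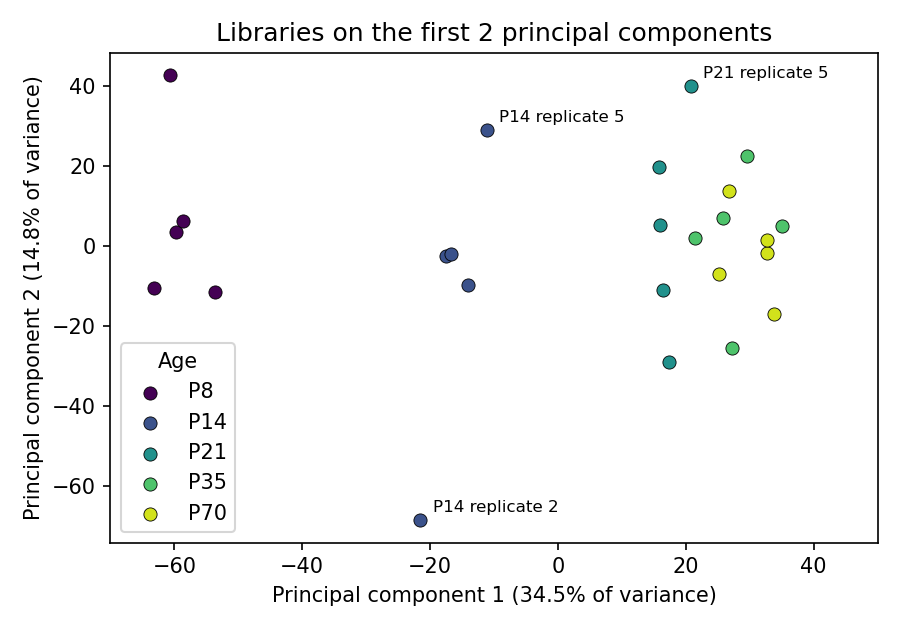
Each point is 1 library, placed on principal components 1 (x axis, 34.5% of variance) and 2 (y axis, 14.8%) of log2(FPKM + 0.5), without units, and coloured by age. Component 1 runs from -63.2 at P8 to 35.1 at P35, and P14 replicate 2 lies at -68.7 on component 2.

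Between P8 and P14 the tissue changed in both directions. Of 14128 gene IDs, 1925 rose and 2165 fell (limma, adjusted p under 0.05), 4090 in all or 28.95%. Most changes were modest, with a median size of 0.54 log2 units among those called, and 249 rose and 254 fell by at least 1 log2 unit. ENSRNOG00000013484, among the largest rises over the whole span, went from 0.5 ± 0.22 to 2.8 ± 0.368 FPKM (SD, n = 5; log2 change 1.74 ± 0.15 SE, limma adjusted p = 6.95e-09). ENSRNOG00000018992, among the largest falls, went from 221 ± 28.7 to 83.2 ± 14.8 FPKM (SD, n = 5; log2 change -1.41 ± 0.16 SE, limma adjusted p = 3.85e-07). The 5 P8 and 5 P14 libraries did not overlap at 2839 gene IDs, 20.09% of those tested, against 0.79% by chance. The 5 largest rises were 2.22 to 3.38 log2 units. The 5 largest falls were -4.71 to -7.59, but all 5 belonged to 155 gene IDs that also swung between under 1 and at least 10 FPKM within an age. With FPKM totals made equal between libraries, 514 gene IDs were called, 77.6% of them higher at P14 against 47.1% with the values as deposited. Rises also came to 55.8% after quantile normalization, 51.7% after median-of-ratios scaling and 55.1% with a mean of at least 5 FPKM, and to 50.2%, 51.7% and 50.7% without P8 replicate 4, P14 replicate 3 or P14 replicate 5.

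Between P14 and P21 falls outnumbered rises. A total of 2458 gene IDs changed, 730 upward and 1728 downward (limma, adjusted p under 0.05), with 76 rising and 108 falling by at least 1 log2 unit. ENSRNOG00000015763 rose from 1.11 ± 0.326 to 9.76 ± 0.983 FPKM (SD, n = 5; log2 change 2.7 ± 0.16 SE, limma adjusted p = 1.31e-10). ENSRNOG00000018992 fell further, from 83.2 ± 14.8 to 11.7 ± 2.23 FPKM (SD, n = 5; log2 change -2.79 ± 0.16 SE, limma adjusted p = 5.91e-11). P14 and P21 libraries did not overlap at 12.99% of the gene IDs tested, against 0.79% by chance. The size of this excess depended on the scaling: rises made up 29.7% of the calls as deposited, 19.2% with FPKM totals made equal, and 46.2% and 49.4% after quantile and median-of-ratios scaling, which center the changes. The count was 1411 with the first title number as a random block, 156 with equal FPKM totals and 1580 without the 3 libraries of lowest same-age correlation, the last chosen after seeing the data.

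Between P21 and P35 far fewer gene IDs changed. There were 229 calls, 77 upward and 152 downward (limma, adjusted p under 0.05), and 9 rose and 7 fell by at least 1 log2 unit. ENSRNOG00000015763 reached 28.9 ± 5.39 FPKM at P35 (SD, n = 5; log2 change 1.51 ± 0.16 SE, limma adjusted p = 8.64e-06), the largest rise among gene IDs selected for this step. The selected falls were -0.88 to -1.41 log2 units. ENSRNOG00000018992 fell to 7.15 ± 1.29 FPKM (SD, n = 5; log2 change -0.67 ± 0.16 SE, limma adjusted p = 0.0304). Libraries of the 2 ages did not overlap at 3.68% of gene IDs. Rises made up 33.6% of calls as deposited, 49.5% after median-of-ratios scaling and 66.7% with equal FPKM totals. The count depended on the fit: it was 78 with the first title number as a random block, 74 from the 10 libraries of these ages alone and 3 with equal FPKM totals, and it rose to 435 and 471 under quantile and median-of-ratios scaling. It fell to 123 without P21 replicate 3, 138 without P35 replicate 2, 144 without P21 replicate 4, 145 without P21 replicate 2 or P35 replicate 1, and 151 without P35 replicate 3. Without P35 replicate 5 rises outnumbered falls, 174 to 131.

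Between P35 and P70, the longest interval at 35 days, 17 gene IDs changed, 6 upward and 11 downward (limma, adjusted p under 0.05; 662 at an unadjusted p under 0.05). The 5 largest falls were -2.17 to -2.36 log2 units each, and together these 5 gene IDs averaged 257 ± 76.9 FPKM at P35 and 55.4 ± 22.8 at P70 (SD over libraries, n = 5). The same group averaged 135 ± 30.2 FPKM at P8, 117 ± 20.8 at P14 and 245 ± 126 at P21 (SD, n = 5). Apart from this group the only gene ID listed was a rise of 0.64 log2 units. In all, 7 gene IDs met the criteria for this step, but the rule lists at most 5 falls. ENSRNOG00000015763 was at 28.9 ± 5.39 FPKM at P35 and 29.1 ± 3.64 at P70 (SD, n = 5), and ENSRNOG00000018992 at 7.15 ± 1.29 and 7.06 ± 1.17 (SD, n = 5). Libraries of P35 and P70 did not overlap at 1.02% of gene IDs, close to the 0.79% of chance. Rises made up 35.3% of the calls as deposited and 14.3% with equal FPKM totals. The split also moved with single libraries, to 6 and 6 without P35 replicate 4, 5 and 6 without P70 replicate 3 or 4, 2 and 10 without P70 replicate 1, 2 and 9 without P35 replicate 1 or P70 replicate 2, 1 and 6 without P35 replicate 2, 3 and 11 without P70 replicate 5, and 9 and 18 without P35 replicate 5. The count was 5 with the first title number as a random block, 7 from these 10 libraries alone, 7 with equal FPKM totals, 28 after quantile normalization and 41 after median-of-ratios scaling. It was 7 without P35 replicate 2, 11 without P35 replicate 1, P70 replicate 2, P70 replicate 3 or P70 replicate 4, and 27 without P35 replicate 5.

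**Figure D2:**
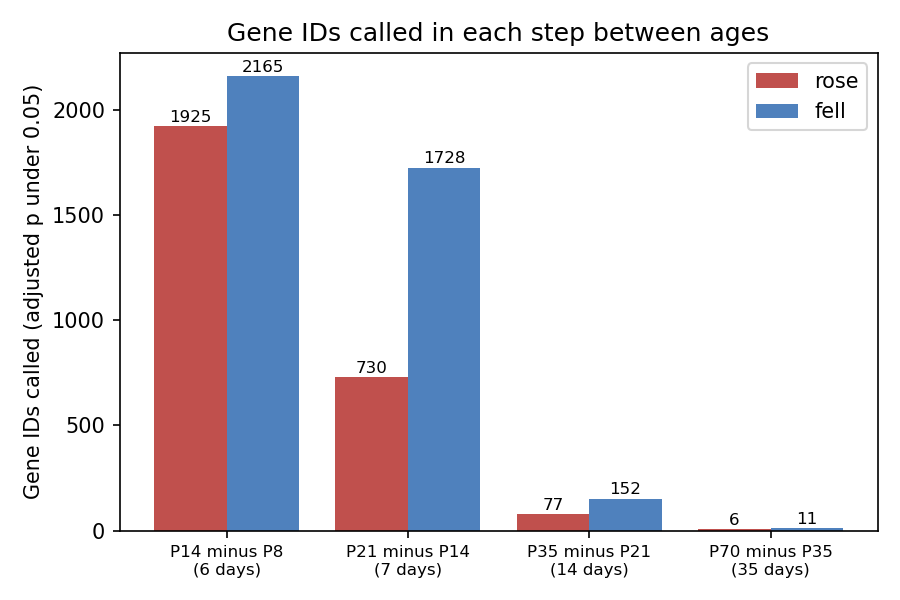
Bars give the number of gene IDs called higher (rose) or lower (fell) at the older age in each step (limma, adjusted p under 0.05), with the length of each interval in days on the x axis. Counts fall from 1925 and 2165 between P8 and P14 to 6 and 11 between P35 and P70.

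Over the whole span, from P8 to P70, 2810 gene IDs rose and 4892 fell (limma, adjusted p under 0.05), 7702 in all. By at least 1 log2 unit, 796 rose and 1195 fell. The rising group had a median of 3.11 FPKM at P8 and 9.7 FPKM at P70, and the falling group 10.4 and 3.41 FPKM. At least 10 FPKM was reached at P8 by 149 of the 796 rising and 617 of the 1195 falling gene IDs, and at P70 by 392 and 284. A log2 change of at least 3 in size was seen in 19 that rose and 38 that fell. ENSRNOG00000015763 rose from 0.246 ± 0.181 to 29.1 ± 3.64 FPKM (SD, n = 5; log2 change 5.33 ± 0.16 SE, limma adjusted p = 2.63e-17). ENSRNOG00000013484 rose from 0.5 ± 0.22 to 27.4 ± 3.09 FPKM (SD, n = 5; log2 change 4.82 ± 0.15 SE, limma adjusted p = 2.63e-17). ENSRNOG00000018992 fell from 221 ± 28.7 to 7.06 ± 1.17 FPKM (SD, n = 5; log2 change -4.88 ± 0.16 SE, limma adjusted p = 5.34e-17). ENSRNOG00000034416 had the most negative selected change, -5.19 ± 1.19 (SE, limma adjusted p = 0.000755), but its levels switched between libraries. It was at 95.2 to 172 FPKM at P8 and 33.7 to 45.6 at P21, while at P14 it was 0.876 FPKM in replicate 1 and listed at 0 in the other 4 libraries. At P70 it was 40.4 and 27.1 FPKM in replicates 1 and 2, 0.774 in replicate 4, and listed at 0 in replicates 3 and 5. It shows no overlap between P8 and P70, but no steady decline.

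The excess of falls depended on the scaling. The median log2 change of all tested gene IDs from P8 to P70 was -0.16 as deposited, and -0.02 after quantile normalization and after median-of-ratios scaling. Both center the changes, which by itself brings the 2 directions closer, so the balance of rises and falls is left open. Rises numbered 2810 against 4892 falls as deposited, 3841 against 3970 after quantile normalization, 3860 against 3922 after median-of-ratios scaling and 1231 against 1211 with FPKM totals made equal. Libraries of P8 and P70 did not overlap at 43.99% of gene IDs, against 0.79% by chance. Near-complete switches were rare. At least 1 FPKM in all P8 libraries and under 0.1 FPKM in all P70 libraries was seen for 6 gene IDs, and the opposite for 2.

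**Figure D3:**
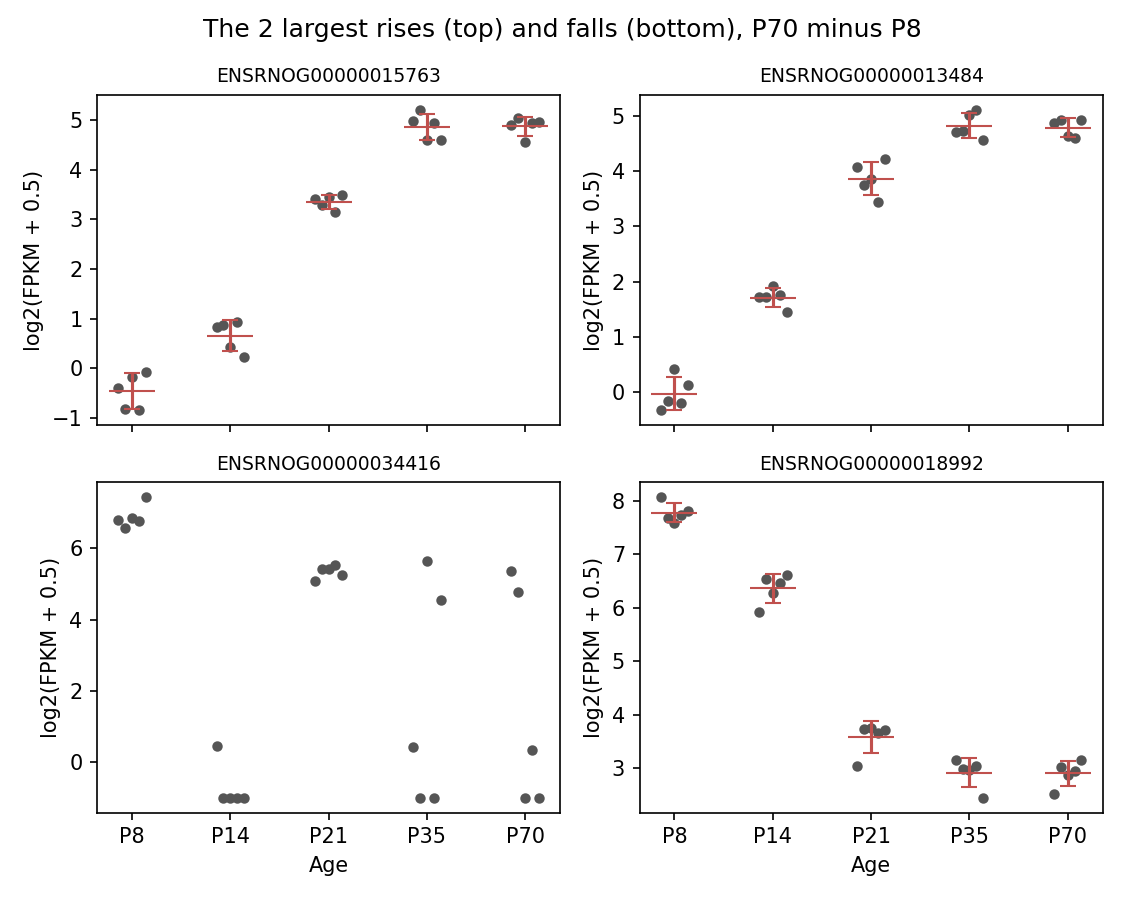
Points are single libraries on the log2(FPKM + 0.5) scale (y axis) at each age (x axis), and red bars are the mean ± SD (n = 5), left out for the gene ID listed at 0 in some libraries. The 2 rising gene IDs end at 29.1 and 27.4 FPKM at P70, ENSRNOG00000018992 ends at 7.06 FPKM, and ENSRNOG00000034416 switches between libraries of P35 and of P70.

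Most of the lasting change was in place by P21. Among the 796 gene IDs that rose by at least 1 log2 unit from P8 to P70, the median share of the change reached was 50.2% at P14, 83.7% at P21 and 96.7% at P35. Among the 1195 that fell it was 46.2%, 83% and 94.2%. The largest single step was from P8 to P14 for 525 of the rising gene IDs (66%) and 679 of the falling ones (56.8%). The step from P14 to P21 was the largest for 190 (23.9%) and 449 (37.6%), and the step from P35 to P70 for 18 (2.3%) and 20 (1.7%). These shares describe gene IDs selected on the P8 and P70 libraries themselves and carry no test.

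**Figure D4:**
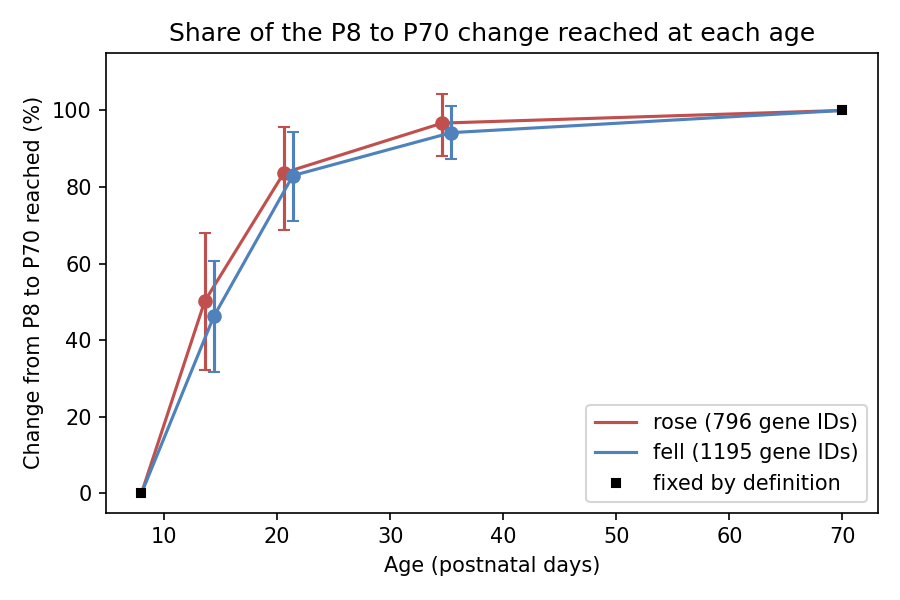
Lines give the median share of the P8 to P70 log2 change reached (y axis, percent) at each age (x axis, postnatal days) for 796 gene IDs that rose and 1195 that fell by at least 1 log2 unit, with bars from the lower to the upper quartile. Points are shifted slightly sideways for legibility, and the medians at P21 are 83.7% and 83%.

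Changes from P8 to P14 tended to run on in the same direction from P14 to P21. Of the gene IDs called between P8 and P14, 436 rose again and 817 fell again between P14 and P21, against 99.5 and 264.8 for independent lists of those sizes. Rises followed by falls numbered 85, and falls followed by rises 33, against 235.4 and 111.9. Both steps share the P14 libraries, whose chance errors push the steps in opposite directions.

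A smaller set peaked or dipped on the way. At P14, 296 gene IDs were above both P8 and P70, and 67 were below both (limma, adjusted p under 0.05 for each). With the P14 libraries split so that each comparison used its own, the medians over 10 splits were 146.5 and 24.25, from smaller groups. At P21, 81 peaked and 46 dipped, and at P35 the counts were 6 and 2. Of the P14 peaks, 6 differed from both ends by at least 1 log2 unit, as did 5 of the dips. With the first title number as a random block there were 164 peaks and 34 dips at P14, and with equal FPKM totals 12 and 0. The dips numbered 113 after quantile normalization, 154 after median-of-ratios scaling and 26 with a mean of at least 5 FPKM. Among recovered gene IDs alone, an alternative chosen after seeing the data, there were 174 peaks and 38 dips.

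The size of each step, the mean squared log2 difference less the part due to spread within ages, compares the steps without a threshold. It was 0.175 ± 0.0292 (jackknife SE, n = 5 per age) from P8 to P14 and 0.0742 ± 0.0381 from P14 to P21. It was 0.0137 ± 0.0197 from P21 to P35 and -0.00213 ± 0.0209 from P35 to P70. None of these last 3 sizes exceeded 0 by 2 SE. With 1 library left out, the last 2 ran from 0.006 (without P21 replicate 3) to 0.0264 (without P21 replicate 1) and from -0.00924 (without P35 replicate 4) to 0.0117 (without P35 replicate 3). A negative size means only that no change was detectable above the noise. Per day, the first 2 sizes were 0.0292 and 0.0106. Over the whole span it was 0.537 ± 0.0317.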

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

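The tests of spread, scaling and title numbers, the depth of P14 replicate 2, the age-specific distances, the predicted reads and the correlation of short gene IDs were chosen after the results were seen, as was the reading of the first wrong-label test, and the others in this part were set beforehand. A library far from the other 4 of its age was looked for in 55 groups of values, and 3 were found, where chance alone gives about 2.8. ENSRNOG00000034416 was at 172 FPKM in P8 replicate 5, against 95.2 to 116 in the others. The same gene ID was at 0.876 FPKM in P14 replicate 1 and listed at 0 in the other 4. Beside 4 values of 0, any value above 0 would be found by this rule. ENSRNOG00000018992 was at 7.71 FPKM in P21 replicate 1, against 12.2 to 12.9 in the others.

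The decline in calls from the first step to the last was weighed first. All contrasts shared 1 spread per gene ID, so a larger spread at the later ages could not by itself lower the later counts. The noise-corrected step sizes also argue against it: their difference, first minus last, was 0.177 ± 0.0359 (SE). Lower depth is argued against by thinning: with all libraries thinned to a relative depth of 0.386, a median of 2102.5 gene IDs was called between P8 and P14 and 10 between P35 and P70. Under 3 other scalings the first step still had at least 73.4 times the calls of the last. Batches that follow the ages cannot be told apart from age, since 0 first title numbers recur at more than 1 age. Age itself, which the design names, stays open and untested, as the intervals also differ in length.

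Grouping by age was set against other groupings of the same libraries. For the F-test, 1 of 100 groupings, the real one, reached 7848 calls, and the highest other gave 35. For P14 minus P8, 1 of 100 splits reached 4090, with 1137 as the highest other. For P21 minus P14 it was 1 of 100 at 2458, with 760 as the highest other, for P35 minus P21 1 of 100 at 229, with 2, and for P70 minus P8 1 of 100 at 7702, with 3317. At the 0.05 level chance can be excluded for these only if all libraries of an age are independent. The splits did not keep libraries with the same first title number together, and the consensus correlation within a number was 0.33. For P70 minus P35, 4 of 100 splits, the real one included, reached 17 calls, and the highest other gave 1378. That passes the same level, but a split with so many calls points to a structure of these 10 libraries other than age. It put P35 replicates 2 and 5 with P70 replicates 2, 3 and 4, whose median log2 values were 2.501 to 2.737, against 2.701 to 2.918 in the rest. Of the 4 pairs of libraries that share a first title number, it parted 2 and kept 2 together. In 100 shuffles of residuals among all 25 libraries, 1 gave more calls for P35 minus P21 than the real ages did, 1031.

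P14 replicate 2, P14 replicate 5 and P21 replicate 5, the libraries of lowest same-age correlation, lay apart from their ages by that measure. Over all tested gene IDs 2 of these 3 were nearest to their own age, and P14 replicate 5, nearer to P21, met the condition set beforehand for a wrong age label, but only 17 of all 25 libraries were nearest to their own, so that distance was read as undecided once seen. Gene IDs that differ with age were then called without the library in question. Over those, 3 of these 3 libraries and 20 of 25 were nearest to their own age. That argues against a wrong label for these 3. The same distance placed 15 of 15 libraries of P8, P14 and P21, but 5 of 10 of P35 and P70. By that distance, scaled by spread, P35 replicate 5 (1.88), P35 replicate 4 (1.71) and P70 replicate 3 (1.62) also lay far out. P14 replicate 2, P14 replicate 5 and P21 replicate 5 lay at 1.63, 1.98 and 1.68. Low depth is argued against by the depth of P14 replicate 2, 1.211, the highest at P14, and by thinning over recovered gene IDs, where the same-age libraries other than P14 replicate 2 stayed at least 0.036 and 0.021 above P14 replicate 5 and P21 replicate 5, whose mean correlations with them were 0.926 and 0.92. The trend of the deviations with transcript length was the strongest of its age in 0 of the 3 (rho 0.108, -0.121 and -0.099), but neither P14 library lay below the median of the others, the bound set beforehand for excluding length, so length stays open, as do dissection and RNA quality, which were not tested.

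The last pattern concerns 155 tested gene IDs (1.1%) that were under 1 FPKM in some libraries and at 10 FPKM or more in others of the same age. They were short: the 133 with a known relative length had a median of 0.0406, against 1.02 for the other gene IDs. The other libraries of the age predicted a median of 19.2 reads for the 218 near-0 values. The gene IDs were selected for reaching 10 FPKM or more in such libraries, which raises the prediction. Too few reads therefore stay open. The deviations of the switching gene IDs had a mean correlation of 0.237, above all 100 sets matched on length (highest 0.157). Those sets were not matched on level or spread, while the switching gene IDs were selected for large swings within ages. The comparison therefore cannot decide whether many of them share a state of the library. Such a state could be size selection or an estimate that fails for short transcripts. Reads shared between near-identical copies were not tested, and no biological explanation was tested.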

How the results depend on the processing

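No list test was run, since the IDs have no names here. The log2 changes from P8 to P70 of the 4 printed gene IDs kept their sign in each alternative that gave a value, and their changes in single steps were not run under alternatives. The counts stayed within 1.5 times under pseudocounts of 0.1 and 1, robust moderation, the covariate, without the 2 shallowest libraries, and with only gene IDs above 0 throughout; the last 3 were chosen after seeing the data. In the order F-test, P14 minus P8, P21 minus P14, P35 minus P21, P70 minus P35, P70 minus P8, equal FPKM totals gave 2216, 514, 156, 3, 7 and 2442 calls. At P8 the totals were 977683 ± 398879 (SD, n = 5), while the median log2 values were 2.84 ± 0.0111 (SD, n = 5). Equal totals therefore move libraries of like median level apart at that age. How much of the lower counts this explains was not tested. A mean of at least 5 FPKM gave 4775, 2533, 1591, 127, 8 and 4672, with fewer gene IDs tested (8156). Requiring a log2 change of at least 1 left 503, 184, 16, 8 and 1991 in the 5 contrasts. Among 9468 recovered gene IDs, chosen after seeing the data, the F-test gave 4956 and the contrasts 2490, 1499, 132, 18 and 4946, and limma-voom gave 5019, 2632, 1548, 145, 19 and 4979.

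Quantile normalization gave 435 and 28 calls for P35 minus P21 and P70 minus P35, median-of-ratios scaling 471 and 41, and the 10 libraries alone 74 and 7. No filter gave 27 for P70 minus P35. The first title number as a random block, with a consensus correlation of 0.33, gave 1411, 78 and 5 from P21 minus P14 on. The 11 library pairs sharing a number had a mean residual correlation of -0.14, against -0.26 in 39 other pairs. Residuals from an age mean correlate negatively by construction. The higher value in pairs sharing a number, not its sign, therefore bears on their likeness. No paired analysis was possible because the numbers do not recur across ages. Without the 3 libraries of lowest same-age correlation P21 minus P14 had 1580 calls, of which 1445 were shared. Array weights gave 4523, 1301 and 65 for the later steps, and both alternatives were chosen after seeing the data. In these the cause was not tested.

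Leaving out each library in turn gave 7207 to 8117 calls for the F-test, 3441 to 4294, 1948 to 2736, 123 (without P21 replicate 3) to 305, 7 (without P35 replicate 2) to 27 (without P35 replicate 5), and 7163 to 7933. The size of P14 minus P8 moved from 0.175 to 0.238 and 0.142 with pseudocounts of 0.1 and 1, 0.111 without a filter and 0.117 with equal FPKM totals, which put P35 minus P21 at -0.0579 and the shares reached at P14 at 62.6% for rises and 33.6% for falls. Depth limits the shallow libraries: with all thinned to 0.386, P35 minus P21 had a median of 73.5 calls, against 132 without thinning.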

Other observations

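The direction test below was chosen after a related correlation between the same steps was seen. The 5 gene IDs that fell together from P35 to P70 were also compared within ages. Their deviations from the age means had pairwise correlations of 0.44 to 0.92 over the 25 libraries. Their group mean was 28.3 to 76.4 FPKM in the P70 libraries, below the 98.7 to 167 FPKM of the P8 libraries and the 199 to 382 FPKM of the P35 libraries. It reached 459 FPKM in the highest P21 library. The 5 were singled out after their values were seen. No other gene IDs were compared, so it stays open whether their correlations are unusual.

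Whether the early change goes on after P21 was tested on separate libraries. Of the gene IDs called between P8 and P14, 52.5% had the same sign from P21 to P70. Of 100 shuffles of the residuals among libraries 35 reached this, with a highest value of 64.9%. Continued change in the same direction after P21 was not detectable beyond the shuffled range. That range was wide, so the test does not show that change stopped. ENSRNOG00000015763, called between P8 and P14, rose on from P21 to P35 (log2 change 1.51 ± 0.16 SE).

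The most abundant gene ID averaged 123522 FPKM, reached 366500, and held a mean of 16.5% of the FPKM total where it was above 0. It is listed at exactly 0 in 5 libraries: P8 replicate 2, P21 replicate 1, P35 replicates 1 and 2, and P70 replicate 1. The lowest value in the other 20 was 34193 FPKM. Whether these zeros mark absent transcripts or failed estimates was not tested, and the FPKM totals of those 5 libraries depend on it.

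The 5 largest falls from P8 to P14 correlated with each other over the 25 libraries at 0.89 to 0.96, and 4 of them were among the 5 largest rises from P14 to P21. The correlations include the age differences by which the 5 were selected, so high values were partly built in. Both lists use the same P14 libraries, so low values at P14 favour the overlap, which was not tested. Of the 155 switching gene IDs, 15 were called by the F-test.

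P35 and P70 were not separated by nearest age: over gene IDs that differ with age, 15 of 15 libraries of P8, P14 and P21 but 5 of 10 of P35 and P70 were nearest to their own age.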
